A study of Mus musculus with 9 samples.

How the data were processed

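RNA from ileal epithelial cells of male NOD mice at postnatal day 23 was extracted with TRIzol and column cleanup, per the labels' protocols, and hybridised to a mouse immunology probe panel on the nCounter platform. In this assay each transcript is caught by a capture probe and a reporter probe with a colour code, and molecules are counted by imaging without amplification. Each deposited library file held whole-number counts per probe, unnormalised, for 547 endogenous genes, 14 housekeeping genes, 8 negative-control and 6 positive spike-in probes, with the class of each probe named per the file headers. No counting software or version is given in the sources used here. The lowest endogenous count in any library was 1, which was the value of 10 to 38 genes per library. A further deposited table held a normalised signal for the 547 endogenous genes. Its values equalled the deposited counts times 1 factor per library, and that factor was 7047 divided by the library's arithmetic mean of the 14 housekeeping counts, with a relative deviation of at most 1.8e-11. The factor ran from 0.734 to 1.82. This scaling was found from the values, since no header or label records it. Scaling by housekeeping counts carries any change of those genes into every other gene. Housekeeping genes took 15% to 24.5% of the counts, and the top share was in control replicate 3. Every control library, at 19% or more, lay above every antibiotic and transfer library, at 18.1% or less, so this scaling differs by group.

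Groups were taken from the sample descriptions (control, 1PAT antibiotics, cecal material transfer), with 3 libraries in each, all marked as batch 1. Within a group, libraries correlated between 0.888 and 0.98 in log2 CPM, and the least different pair had a chi-square of 6.75 per degree of freedom, so none was counted as a duplicate.

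Tests ran on the deposited counts with edgeR 4.0.16 in R 4.3.3. A gene was kept where its count exceeded the library's negative-control mean plus 2 SD in at least 3 of the 9 libraries. That limit lay between 7.74 and 17.7 counts. Of the 561 genes 470 were kept, 456 of them endogenous, and 91 endogenous genes were left out. Scaling factors came from TMM over the kept genes (0.837 to 1.1). The quasi-likelihood test (glmQLFit, glmQLFTest, not robust) used 1 fit of all 9 libraries with 6 residual degrees of freedom and no covariates. Benjamini-Hochberg adjusted p-values ran over the 470 genes, with a threshold of 0.05. The common dispersion was 0.174, a biological coefficient of variation of 41.7%. Fold changes are given on the log2 scale with the standard error implied by the test, and levels as TMM-scaled CPM. An exact permutation of 3 libraries against 3 cannot give a p under 0.10, so no such test was used for single values.

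Before the data were examined, 27 gene lists were fixed from textbook knowledge. The 26 with at least 3 kept members were tested with camera (limma 3.58.1), which compares a list with the rest of the panel, at a preset inter-gene correlation of 0.01 and an adjusted p under 0.05 over the lists of a comparison. The same test with an estimated correlation, and fry, which asks whether a list's genes move on balance one way, were run beside it. The autophagy list kept 2 members and was not tested. Lists share members: Cxcr5, Btk, Cr2, Ccl5, Xcl1, Ifng, Fasl and Thy1 of the lymphocyte lists are also in others, as are 4 of the 5 epithelial markers (Ccl25, Defb1, Il18 and Pigr) in the mucosal defence list. A list score is the mean log2 CPM of its kept members with a prior count of 2. The named genes followed a rule fixed at the same time. Since fewer than 10 genes passed in each comparison, the 10 with the smallest p were named, plus up to 4 members with the smallest p of each list that was called.

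Alternatives were DESeq2 1.42.0, limma-voom, a robust quasi-likelihood fit, upper-quartile, housekeeping and spike-in scaling, other filters, background subtraction, 2-group fits, the replicate number as a block, the deposited signal with limma on log2(value + 1), other thresholds, and leaving out each library. The arithmetic housekeeping mean as scale, and the antibiotic and transfer libraries combined against control, were added after the data were seen.

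The procedure was tested on simulated data with the real means, dispersions and library sizes for antibiotic against control. With 200 of 470 genes changed in 10 data sets, it recovered 25.9% of genes changed 2-fold and 82.1% of genes changed 4-fold, and 3.23% of its calls were false. A list raised by 1 on the log2 scale was called in 10 of 10 data sets, and unchanged lists in 0 of 10. The simulated genes were independent of each other. In the lists called for antibiotic against control, the correlation estimated from the data ran from 0.128 (interferon) to 0.642 (T cells), above the preset 0.01. The simulated runs therefore do not give the rate of false calls for such lists. Panel genes were named as in the files. Of the 561 RefSeq identifiers 549 matched a gene table of the mouse assembly GRCm38.p6, and 13 of these have another current symbol there. The sources used here name no genome build, so no coordinates are given. Figures were drawn with matplotlib 3.10.9.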

Results

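Expression of a mouse immunology gene panel was measured in ileal epithelial cells of male non-obese diabetic (NOD) mice, an inbred strain that develops autoimmune diabetes spontaneously, at postnatal day 23. The 9 libraries form 3 groups of 3, namely untreated control mice, mice given antibiotics, and mice given a transfer of cecal material. The series title frames the transfer as a rescue after antibiotic exposure, while the labels do not say whether the transfer mice had received antibiotics first. The panel held 547 endogenous and 14 housekeeping genes. Total counts over these genes ran from 323129 in antibiotic replicate 2 to 747434 in transfer replicate 2, a range of 2.31 times. Between 337 and 478 genes per library exceeded the limit set by that library's negative-control probes, and 470 genes were kept for testing. B2m, the light chain of MHC class I, was the most abundant gene and took between 11.4% and 20% of a library's counts, with the top value in control replicate 3. Nothing in the labels says that the 3 libraries of a group came from separate animals, so the p-values measure the spread between these libraries.

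Control replicate 3 stood apart from the other 8 libraries. On the leading principal component, which held 52.4% of the variance, it lay at -27.5, while the others lay between -7.3 and 11.7. Its T cell score, the mean log2 CPM (TMM-scaled) of 15 T cell genes, was 6.65, against 8.45 in control replicate 1 and 7.94 in control replicate 2. Its B cell score was 6.13, against 7.83 and 7.20 in those libraries. Its score for MHC class I presentation and proteasome genes was the highest of all 9 libraries, at 11.32. The epithelial marker score was also highest there, at 11.60. Synthetic spike-in totals differed by 11.8 times between libraries, from 2994 in transfer replicate 1 to 35248 in antibiotic replicate 2, and averaged 28354 ± 7805 in antibiotic, 11642 ± 11174 in control and 8516 ± 5159 in transfer libraries (SD, n = 3).

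**Figure D1:**
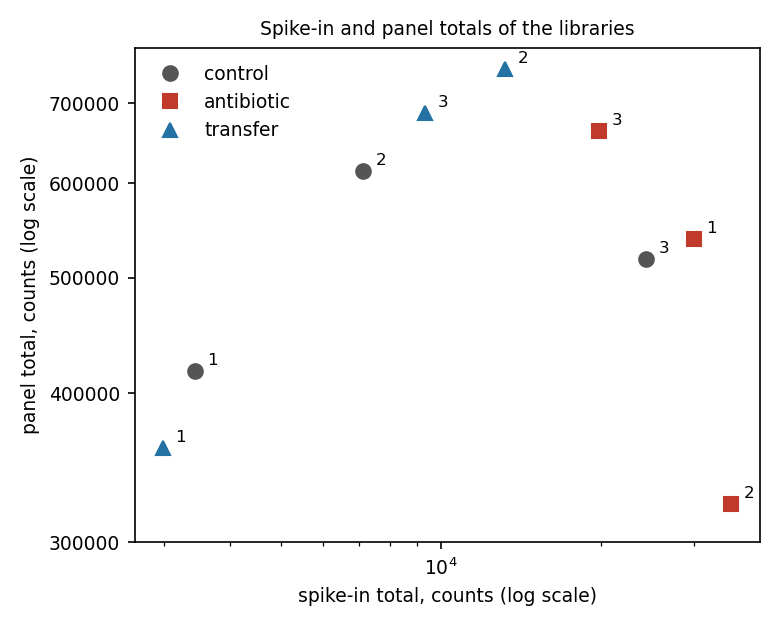
Spike-in total (x axis, counts, log scale) against panel total (y axis, counts, log scale) of the 9 libraries, with 1 point per library, marked by group and numbered by replicate. Spike-in totals spread 11.8 times while panel totals spread 2.31 times, and the antibiotic libraries lie at 19879 or more spike-in counts.

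The antibiotic and control groups address which ileal epithelial transcripts differ after antibiotic exposure. Lymphocyte gene lists were higher in the antibiotic libraries relative to the rest of the panel, while spike-in scaling, which moved the median of all genes by -1.85 (log2), placed nearly all of their members lower. The list of CD8 and cytotoxic intraepithelial lymphocyte markers, the T cells that reside between epithelial cells, had 16 of 17 members higher, with a median log2 fold change of 1.06 (camera adjusted p = 0.00052). B cell markers had 12 of 13 members higher, with a median of 0.97 (camera adjusted p = 0.00183), and T cell markers 13 of 15, with a median of 0.90 (camera adjusted p = 0.0083). Interferon-stimulated genes were lower, in 13 of 15 members, with a median of -0.64 (camera adjusted p = 0.00562). In all 8 lists that passed, including these, the call was lost with the correlation between members estimated from the data (adjusted p = 0.652 with an estimated correlation, for each). With spike-in scaling the cytotoxic list had a median of -1.10, the T cell list -1.24, the B cell list -1.15 and the interferon list -2.22, so directions hold relative to the panel and not to the spike-ins. Dendritic cell markers, with a median of 1.01, and granulocyte and mast cell markers, with 0.83, lay beside the lymphocyte lists without passing (camera adjusted p = 0.31 for each). By single genes, 0 of 470 passed at an adjusted p under 0.05.

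Among the cytotoxic intraepithelial lymphocyte markers, 0 genes passed over all genes tested and 8 passed when adjusted over the list alone, all of them higher. Klrd1, an NK and cytotoxic T cell receptor chain, measured 3756 ± 766 CPM in antibiotic and 1204 ± 589 CPM in control libraries (SD, n = 3), a log2 fold change of 1.64 ± 0.41 (SE), which was -0.64 with spike-in scaling. Ifng, the effector cytokine interferon gamma, measured 430.4 ± 88.9 against 118 ± 71.5 CPM, and Fasl, a death receptor ligand of cytotoxic cells, 681 ± 148 against 281 ± 137 CPM. Runx3, a transcription factor of the CD8 lineage, had a log2 fold change of 1.70 ± 0.55 (SE). The B cell list had 0 members passing over all genes and 2 adjusted over the list alone. These were Ms4a1, which encodes CD20, at 2954 ± 707 against 744 ± 439.7 CPM, and Cxcr5, the follicle-homing chemokine receptor. Cxcr5 measured 88.5 ± 30.5 against 22.2 ± 2.58 CPM, with 2 of 3 control libraries above the background limit. The other leading members of the B cell list were Cr2, at 1.27 ± 0.52, and Cd79b, at 1.19 ± 0.50 (log2, SE). In the T cell list 1 gene passed adjusted over the list alone, Cd28, a co-stimulatory receptor, with a log2 fold change of 1.47 ± 0.40. Cd3d had 1.22 ± 0.43, Cd4 1.43 ± 0.58 and Cd2 1.23 ± 0.55 (log2, SE). Without control replicate 3, Cd3d had 0.77, Cd2 0.74 and Cd79b 0.72, and without control replicate 1, Cd2 had 1.88 and Cd79b 1.89.

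The list of chemokine receptors had 13 of 14 members higher, with a median of 0.92 (camera adjusted p = 0.0083), and the regulatory T cell and checkpoint list had 16 of 22 higher, with a median of 0.44 (camera adjusted p = 0.0428). Adjusted over the list alone, 1 chemokine receptor passed, Cxcr5. The next members were Ccr7, a lymph node homing receptor, at 1.33 ± 0.52 (0.86 without control replicate 3) and Ccr6 at 1.42 ± 0.56 (log2, SE). Cxcr2, also among them, was above the background limit in 0 control libraries and 1 antibiotic library, so no fold is given. In the regulatory list 2 genes passed adjusted over the list alone, namely Il2ra, the high-affinity interleukin-2 receptor chain, at 2.09 ± 0.57, and Ctla4, an inhibitory T cell receptor, at 1.72 ± 0.50. Btla had 1.71 ± 0.57 and Icos 1.62 ± 0.56. No member of either list passed over all genes. Control replicate 3 had the lowest score of all libraries in each of these 5 higher lists.

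The lower lists held genes of interferon response, antigen presentation and microbial sensing. Among the interferon-stimulated genes 3 passed adjusted over the list alone and 0 over all genes. Stat2, a transcription factor of type I interferon signalling, measured 108 ± 3.77 CPM in antibiotic and 396 ± 96.3 CPM in control libraries, a log2 fold change of -1.88 ± 0.42 (SE), and Irf7 412 ± 71.7 against 997 ± 216 CPM. Ifi35, which passed adjusted over the list alone with them, had -0.97 ± 0.32 and Irgm1 -1.10 ± 0.40 (log2, SE). The MHC class I and proteasome list had 9 of 11 members lower, with a median of -0.41 (camera adjusted p = 0.0342). In it 2 genes passed adjusted over the list alone, Psmb10, an immunoproteasome subunit, at -1.19 ± 0.35 and Tap1, a peptide transporter, at -1.78 ± 0.53. Psmb9 had -1.02 ± 0.36 (-0.67 without control replicate 3) and Tapbp -0.83 ± 0.48. The list of Toll-like and NOD receptor to NF-kB signalling had 24 of 31 members lower, with a median of -0.34 (camera adjusted p = 0.0132). Its 2 members that passed adjusted over the list alone went opposite ways. Cd14, the lipopolysaccharide co-receptor, measured 700.3 ± 116 against 1874 ± 418 CPM, while Tlr8, an endosomal RNA sensor, measured 88.4 ± 36.3 against 17.4 ± 7.78 CPM and was above the background limit in 1 of 3 control libraries. Tollip, an inhibitor of this pathway, had -0.95 ± 0.30 and Irak1 -1.24 ± 0.50. Control replicate 3 had the highest score of all libraries in each of these 3 lower lists.

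The gene with the smallest p was Ptgs2, the inducible cyclooxygenase, at 189.5 ± 83.7 CPM in antibiotic and 22.8 ± 13.1 CPM in control libraries, an 8.19-fold difference (edgeR adjusted p = 0.0614), with 2 of 3 control libraries above the background limit. Itga4, an integrin chain of gut-homing lymphocytes, had a log2 fold change of 2.02 ± 0.44, Gpr183, an oxysterol receptor that positions B and T cells, 2.07 ± 0.47, and H60a, a ligand of the activating receptor NKG2D, 2.04 ± 0.46. For the 10 genes with the smallest p, every antibiotic library lay on the same side of every control library. Over the panel, 136 genes (28.9%) had such non-overlapping groups, where chance gives 10%. At an unadjusted p under 0.05 there were 102 genes (67 higher, 35 lower), against 23.5 expected of independent genes and 48 in the highest other split of the same 6 libraries.

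The count of 0 is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2 called 51 genes (33 higher, 18 lower), limma-voom 5 higher, and edgeR with upper-quartile factors 12 (4 higher, 8 lower). Leaving out 1 library moved the edgeR count to 23 without control replicate 1, 9 without control replicate 3 and 1 without antibiotic replicate 3. The number of lists called fell to 3 without control replicate 3, when the cytotoxic, B cell and interferon lists still passed, with medians of 0.63, 0.66 and -0.29. The medians of the lists then lost were 0.44 for T cells, 0.46 for chemokine receptors, 0.21 for the regulatory list, -0.18 for MHC class I and -0.35 for microbial sensing. The regulatory list did not pass without antibiotic replicate 1, nor with housekeeping or spike-in scaling, and neither it nor the MHC class I list passed without antibiotic replicate 3. The MHC class I list also did not pass with the geometric housekeeping mean or background subtraction.

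**Figure D2:**
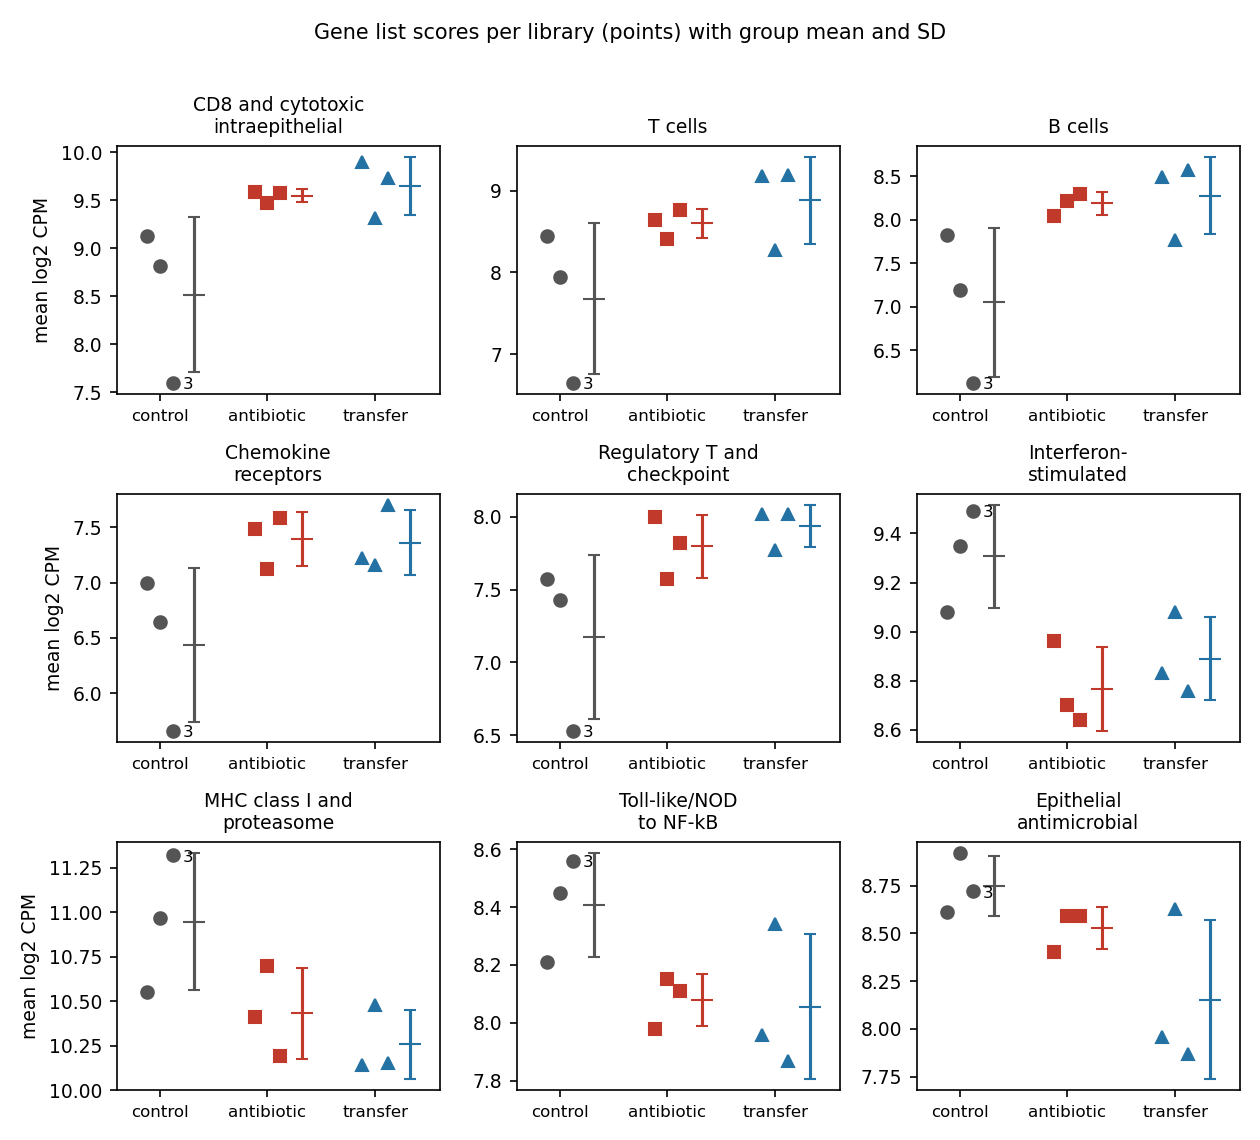
Scores of 9 gene lists (y axes, mean log2 TMM-scaled CPM of the kept members, a separate scale in each panel), with 1 point per library by group (x axes), and bars for the group mean ± SD (n = 3); control replicate 3 is marked 3. For the cytotoxic intraepithelial list the antibiotic libraries lie between 9.47 and 9.59 and the control libraries between 7.6 and 9.13, an order that spike-in scaling turned (median log2 fold change of that list -1.10).

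The transfer and antibiotic groups address whether transfer of cecal material shifts expression away from that of antibiotic mice. No gene passed edgeR, with a smallest adjusted p of 0.993, and no gene list passed camera. Vtn, which encodes the adhesive glycoprotein vitronectin, measured 59.5 ± 49.97 CPM in transfer and 8.98 ± 4.22 CPM in antibiotic libraries, with 70.9 ± 52.2 CPM in control (SD, n = 3); it was above the background limit in 0 antibiotic libraries. Il17f, a type 3 cytokine, measured 6.26 ± 7.32 against 45.5 ± 25 CPM, with 13.5 ± 19.98 CPM in control, and was above the limit in 1 of 3 transfer and 2 of 3 antibiotic libraries. Leaving out transfer replicate 1 moved the log2 fold change of Vtn by 1.51 times, towards 0, and leaving out transfer replicate 2, the only transfer library with Il17f above the limit, moved that of Il17f by 1.61 times, away from 0. No fold is given for either, since each then had a group with no library above the limit.

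None of the 10 genes with the smallest p passed. With spike-in scaling, which moved the median of all genes by 1.95 (log2), Tlr8 lay at 0.50 and Ccl20 at 0.89, opposite to the values that follow. Tlr8 had a log2 fold change of -1.56 ± 0.54, Ccl20, an epithelial chemokine that attracts CCR6-bearing cells, -1.42 ± 0.51, and Cxcl13, the B cell follicle chemokine, -1.76 ± 0.70, with 1 of 3 transfer libraries above the background limit. On the other side stood Gm10499 at 1.90 ± 0.61, the T cell surface protein Cd5 at 1.38 ± 0.48, Stat2 at 1.04 ± 0.42 and the CD8 beta chain Cd8b1 at 1.58 ± 0.69 (log2, SE), for which 1 of 3 antibiotic libraries was above the limit. Mapk11 was above it in 2 transfer and 0 antibiotic libraries, so no fold is given. Without transfer replicate 1, Gm10499 and Cd8b1 each had 1.01, and without transfer replicate 2, Stat2 had 0.58, while no remaining transfer library had Cxcl13 above the limit, so no fold is given for it there. The lists with the smallest adjusted p were epithelial. Epithelial cell markers were lower in 5 of 5 members, with a median of -0.43, and epithelial antimicrobial and mucosal defence genes in 10 of 12, with a median of -0.37 (camera adjusted p = 0.0991 for each; adjusted p = 0.981 with an estimated correlation), and spike-in scaling turned these medians to 1.52 and 1.53. Every other list had a camera adjusted p of 0.496 or more, and in no list did a gene pass, over all genes or adjusted over the list alone.

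By edgeR 12 genes had an unadjusted p under 0.05 (6 higher, 6 lower), against 23.5 expected of independent genes and 48 in the highest other split of the same 6 libraries, and DESeq2 and limma-voom each called 0. Groups did not overlap in 35 genes (7.45%), where chance gives 10%. The 95% interval of a single gene's log2 fold change, without adjustment over genes, had a median width of 1.06 to either side. Smaller differences were not detectable for most genes, and larger ones could be missed too. The simulated data for antibiotic against control recovered 25.9% of genes changed 2-fold. Without transfer replicate 2, camera at the preset correlation called 3 lists, namely T cell markers higher and both epithelial lists lower. An estimated correlation was used only with all libraries, where each of these lists had a camera adjusted p of 0.981.

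The transfer and control groups address whether expression after cecal transfer differs from that of control mice. The 8 lists called for antibiotic against control were called here too, with 1 more. The cytotoxic intraepithelial lymphocyte list was higher in 17 of 17 members, with a median log2 fold change of 1.18 (camera adjusted p = 4.38e-05), T cell markers in 15 of 15, with a median of 1.09 (camera adjusted p = 0.00022), and B cell markers in 12 of 13, with a median of 1.26 (camera adjusted p = 0.000264). MHC class I and proteasome genes were lower in 10 of 11 members, with a median of -0.84 (camera adjusted p = 0.00198). All 9 lists that passed lost the call when the correlation was estimated (adjusted p = 0.564 with an estimated correlation, for each). By single genes, 0 of 470 passed in edgeR, with a smallest adjusted p of 0.181. With spike-in scaling, the medians of the lists that passed kept their direction here. Control replicate 3 had the lowest score of all libraries in the lymphocyte, chemokine receptor and regulatory lists, and the highest in the MHC class I, interferon and microbial sensing lists. Scores of single libraries overlapped in part, as for T cells, where control replicate 1 had 8.45, transfer replicate 2 had 8.27 and antibiotic replicate 2 had 8.41.

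The cytotoxic list had 0 genes passing over all genes and 8 adjusted over the list alone, all higher. Klrd1 measured 3781 ± 849 CPM in transfer and 1204 ± 589 CPM in control libraries (SD, n = 3). Cd160, a receptor of intraepithelial lymphocytes, measured 1141 ± 226 against 504 ± 271 CPM, and Fasl 719 ± 114 against 281 ± 137 CPM, while the activation marker Cd69 had a log2 fold change of 1.2 ± 0.41 (SE). In the B cell list 5 genes passed adjusted over the list alone and 0 over all genes. Ms4a1 measured 2522 ± 827 against 744 ± 439.7 CPM, and Cr2, the complement receptor of B cells, 316 ± 65.5 against 107 ± 69 CPM. Pax5, which specifies B cell identity, had 1.54 ± 0.53 and Ikzf3 1.41 ± 0.48 (log2, SE). No T cell marker passed either adjustment. Cd3d had 1.27 ± 0.43, Lck, a kinase of the T cell receptor, 1.48 ± 0.55, Cd28 1.09 ± 0.40 and Cd7 1.10 ± 0.44. Cd3d had 0.84 and Cd7 0.65 without control replicate 3.

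Chemokine receptors were higher in 14 of 14 members, with a median of 1.03 (camera adjusted p = 0.00605), and regulatory T cell and checkpoint genes in 20 of 22, with a median of 0.71 (camera adjusted p = 0.00753). In neither list did a gene pass, over all genes or adjusted over the list alone. Ccr7 had 1.43 ± 0.52, Cxcr5 1.26 ± 0.50, Cxcr6 1.11 ± 0.44 and Ccrl2 0.97 ± 0.40. Tigit, an inhibitory receptor, had 1.32 ± 0.50, Ctla4 1.22 ± 0.49, Il2ra 1.35 ± 0.56 and Nt5e 0.89 ± 0.36 (log2, SE). In the absence of control replicate 3, Cxcr6 had 0.68, Ctla4 0.77 and Nt5e 0.55.

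Of the lower lists, the MHC class I and proteasome list had 2 genes passing adjusted over the list alone, Tap1 at -1.79 ± 0.53 and Psmb9 at -1.15 ± 0.37, and 0 over all genes. Psmb10 had -0.95 ± 0.35 and Psmd7 -1.14 ± 0.44. The list of Toll-like and NOD receptor to NF-kB signalling was lower in 25 of 31 members, with a median of -0.44 (camera adjusted p = 0.00574), and interferon-stimulated genes in 11 of 15, with a median of -0.69 (camera adjusted p = 0.0153). No member of these lists passed, over all genes or adjusted over the list alone. Cd14 measured 796 ± 182 CPM against 1874 ± 418 CPM in control, Nfkbiz had -0.87 ± 0.35, Tirap -1.21 ± 0.54 and Irak2 -0.78 ± 0.36. Among the interferon genes Irgm1 had -1.18 ± 0.41, Irf1 -0.79 ± 0.32 and Mx1 -1.02 ± 0.48, while Ifitm1 went the other way, at 1.28 ± 0.55 (log2, SE). Leaving out control replicate 3 gave Psmb10 -0.63, Tirap -0.75, Mx1 -0.54 and Ifitm1 0.80. Epithelial antimicrobial and mucosal defence genes were lower in 10 of 12 members, with a median of -0.42 (camera adjusted p = 0.0163). In that list 1 gene passed adjusted over the list alone, Nos2, the inducible nitric oxide synthase, at 104 ± 58 against 391 ± 172 CPM. Xbp1, a regulator of secretory cells, had -0.71 ± 0.31, the alarmin Il33 -1.35 ± 0.62 and Il18 -1.01 ± 0.51. Il18 had -0.53 without control replicate 3 and -1.63 without transfer replicate 2, and Il33 -2.56 without transfer replicate 2. The epithelial marker score, at 10.49 ± 0.36 in transfer and 11.09 ± 0.56 in control libraries, is given beside these groups; its list did not pass (camera adjusted p = 0.126).

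Outside the lists, Itln1, a lectin secreted by goblet and Paneth cells, measured 9474 ± 1991 CPM in transfer and 23380 ± 7879 CPM in control libraries, a 2.47-fold lower level (edgeR adjusted p = 0.181), with every transfer library below every control library. H60a had a log2 fold change of 1.69 ± 0.46, Itga4 1.61 ± 0.44, Gpr183 1.66 ± 0.46 and the chemokine Ccl4 1.49 ± 0.42 (SE). At an unadjusted p under 0.05 edgeR gave 105 genes (71 higher, 34 lower), against 23.5 expected of independent genes and 144 in the highest other split of the same 6 libraries. Non-overlapping groups were found in 124 genes (26.4%), where chance gives 10%. DESeq2 called 40 genes (29 higher, 11 lower) and limma-voom 0. The edgeR count was 2 without control replicate 3, when Itln1 and Pla2g2a passed, and 1 without control replicate 1, when Cdkn1a passed; Pla2g2a and Cdkn1a were named after their values were seen. The 9 lists that passed did so without control replicate 3 too, with medians of 0.81 for the cytotoxic, 0.73 for the T cell, 0.86 for the B cell, 0.73 for the chemokine receptor and 0.40 for the regulatory list. The lower lists then had -0.51 for MHC class I, -0.51 for interferon, -0.39 for microbial sensing and -0.55 for mucosal defence, and the interferon list did not pass over the genes above background in all 9 libraries.

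The return of antibiotic-changed genes towards control was counted as genes called in antibiotic against control and called the opposite way in transfer against antibiotic. There were 0 such genes by edgeR and 0 by DESeq2 and limma-voom, against 0 expected of independent lists and 0 in 100 simulated data sets without group effects. Each method called 0 genes in transfer against antibiotic, so the count could only be 0 and does not measure return. Of the 102 genes with an unadjusted p under 0.05 in antibiotic against control, 78 (76.5%) had the opposite direction in transfer against antibiotic. Without any effect the shared antibiotic libraries gave 91.1% on average in the simulations. These lacked an effect common to antibiotic and transfer libraries. Neither that share nor the simulated count below therefore shows what a common effect without return would give. With an unadjusted p under 0.05 in both, 7 genes went opposite ways, while the simulations without effects gave 4.82 on average, 11 at most, and at least 7 in 21 of 100. These were Ptgs2, Tlr8, Ccl20 and Cxcl13, which were higher in antibiotic libraries and nearer to control in transfer libraries, and Stat2, Vtn and Gm10499, which were lower in antibiotic libraries and higher in transfer libraries. With spike-in scaling Stat2, Vtn, Gm10499 and Cxcl13 kept both directions, Tlr8 (0.50) and Ptgs2 (1.01) were higher in transfer than in antibiotic libraries, and Ccl20 turned in both comparisons (-0.73 and 0.89).

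The fold changes against control were alike in both treated groups. Over the 470 genes, which are not independent replicates, they correlated at 0.806 with a covariance of 0.562. In 100 simulated data sets with shared controls, no effects and independent genes, the correlation was 0.487 and the covariance 0.153 on average. Panel genes are correlated, so these values may be too low for what shared controls give. At an unadjusted p under 0.05, 49 genes were higher in both comparisons and 17 lower in both, while independent lists would share 10.1 and 2.53. Simulated data without effects shared 4.28 genes in the same direction on average and 9 at most. The 3 control libraries were too few to split into sets of at least 2, so part or all of this excess may come from the shared controls.

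**Figure D3:**
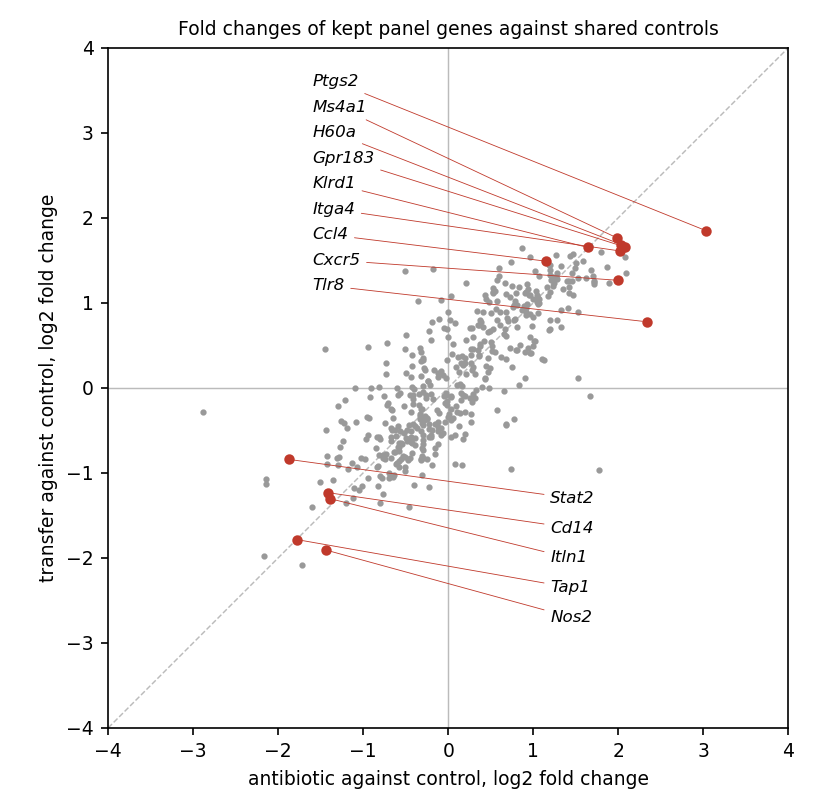
Log2 fold change of antibiotic against control (x axis) and of transfer against control (y axis) for 470 panel genes, with the 10 genes of smallest p in each comparison in red and named, and the line of equal change dashed. Klrd1 lies near that line, at 1.64 and 1.65 (-0.64 in the antibiotic comparison with spike-in scaling). Tlr8, above the background limit in 1 of 3 control libraries, lies at 2.33 and 0.78.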

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

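The arithmetic housekeeping mean as scale was chosen after the data were seen. For antibiotic against control the gene count moved from 0 to 51 by DESeq2, 30 at an adjusted p under 0.10, 12 with upper-quartile factors, 5 by limma-voom and 2 with spike-in scaling, and it ran from 0 to 23 over the fits that left out 1 library. For transfer against control it was 40 by DESeq2 and ran from 0 to 2 with 1 library left out. For transfer against antibiotic, and for the genes called opposite ways, it was 0 in every alternative run. Called lists numbered 8 in antibiotic against control, 9 in transfer against control and 0 in transfer against antibiotic; with an estimated correlation and by fry they numbered 0 in each. With 1 library left out they ran from 3 to 8, from 9 to 10 and from 0 to 3, and in transfer against antibiotic they were 2 at an adjusted p under 0.10 and 1 from the deposited signal. The causes of these differences were not tested.

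Spike-in scaling moved the median of all genes by -1.85 (log2) in antibiotic against control and by 1.95 in transfer against antibiotic; housekeeping scaling moved it by 0.31 and 0.46 in antibiotic and transfer against control. The alternatives together gave 1879 log2 fold changes of named genes, and 20 of these changed sign. All 20 were among the 86 values under spike-in scaling. In antibiotic against control 18 of 35 changed sign: Gpr183 -0.12, H60a -0.16, Ms4a1 -0.16, Klrd1 -0.64, Ctla4 -0.70, Btla -0.54, Icos -0.59, Ccr7 -0.84, Ccr6 -0.66, Cd28 -0.39, Cd3d -1.06, Cd4 -0.50, Cd2 -1.01, Ifng -0.44, Runx3 -0.72, Fasl -0.87, Cr2 -0.90 and Cd79b -1.01. In transfer against antibiotic Tlr8 at 0.50 and Ccl20 at 0.89 did so. Leaving out 1 library moved 22 of the 86 log2 fold changes of named genes by over 1.5 times, most often control replicate 3. A further 77 values newly passed the threshold and 1782 kept both direction and side. For called lists the shift against the rest of the panel kept its sign in all 374 values, and 325 stayed called. With an estimated correlation and by fry the shift was that of the main fit, so its sign could not change. Another scale moves a list and the rest of the panel by nearly the same amount, so little change was possible there either.

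With the replicate number as a block, gene counts were 0 in all 3 comparisons and list counts 8, 0 and 9. The numbers did not pair libraries: of 9 same-number pairs from different groups 2 had deviations correlated over 0.1 (range -0.488 to 0.337), and 1 library matched its own number best. The robust fit, the fold minimum and DESeq2 were not run for lists. For genes with counts near the background limit, such as Il17f, Vtn, Mapk11 and Cxcr2, fold changes are uncertain, and the part of depth was not tested.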

Other observations

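The comparison of antibiotic and transfer libraries combined was added after the lists called against control were seen, before its own splits were run for lists and after for genes. The tests of cell-type shares, of control replicate 3, of shared controls and of spike-in totals were chosen after the results were seen; the splits of each planned comparison were chosen before.

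With TMM scaling, antibiotic and transfer libraries combined, 6 against 3 control libraries, gave 14 genes at an edgeR adjusted p under 0.05 (8 higher, 6 lower), and 13 of the 14 had non-overlapping groups. The higher ones were Klrd1 (log2 fold change 1.65 ± 0.36, SE), Ms4a1 (1.88 ± 0.41), Itga4 (1.83 ± 0.40), Gpr183 (1.88 ± 0.42), the interleukin-7 receptor Il7r (1.70 ± 0.43), the phosphatase Ptpn22 (1.40 ± 0.36), H60a (1.87 ± 0.41) and Ptgs2 (2.55 ± 0.61). The lower genes were Cd14 (-1.32 ± 0.26), Itln1 (-1.35 ± 0.28), Tap1 (-1.78 ± 0.41), the MHC class II transactivator Ciita (-2.07 ± 0.51), Nos2 (-1.66 ± 0.43) and the antimicrobial phospholipase Pla2g2a (-1.50 ± 0.35). Only 1 of 84 splits of the 9 libraries into 6 and 3, the real one, gave 14 genes, and the highest other gave 1. The combination was formed after both groups had been compared with control. That share makes no allowance for this, so it cannot exclude chance. At an unadjusted p under 0.05 the real split gave 141 genes and the highest other 153, and 2 of the 84 splits gave as many, the real one included. Without control replicate 3 the count was 7. Itln1 and Pla2g2a were lower in both comparisons against control without control replicate 3, at -1.69 ± 0.30 and -1.98 ± 0.39 in antibiotic and -1.58 ± 0.30 and -1.78 ± 0.39 in transfer libraries (edgeR adjusted p = 0.00919, 0.0139, 0.0207 and 0.0425). Pla2g2a, Ciita, Il7r and Ptpn22 were named after their values were seen.

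Other gene groups did not pass against control; their medians are on the TMM scale, and with spike-in scaling all were below 0 in antibiotic libraries. Type 3 immunity genes had a median log2 fold change of 0.49 in antibiotic and 0.35 in transfer libraries (camera adjusted p = 0.31 and 0.516), dendritic cell markers 1.01 and 0.83 (0.31 and 0.215), and granulocyte and mast cell markers 0.83 and 0.51 (0.31 and 0.468). Macrophage markers had 0.06 and -0.06 (0.694 and 0.582), plasma cell markers 0.17 and 0.32 (0.928 and 0.642), endothelial and stromal markers 0.31 and 0.65 (0.813 and 0.468), and erythroid and platelet genes -0.52 and -0.57 (0.31 and 0.135). MHC class II genes had -0.17 and 0.04 (0.31 and 0.516), complement genes -0.25 and -0.25 (0.31 and 0.215), and chemokines 0.18 and 0.03 (0.723 and 0.823). Pro-inflammatory cytokines had 0.43 and 0.08 (0.694 and 0.867), JAK-STAT genes -0.06 and -0.17 (0.31 and 0.516), and apoptosis genes -0.27 and -0.28 (0.884 and 0.496). TGF-beta pathway genes had -0.13 and 0.18 (0.461 and 0.516), Fc receptor and immunoglobulin genes -0.01 and 0.48 (0.722 and 0.468), and adhesion genes 0.46 and 0.55 (0.406 and 0.39). The median differed in sign from the mean or the tested shift in several lists. In antibiotic libraries the mean was 0.01 for apoptosis genes, -0.05 for macrophage markers and 0.22 for Fc receptor genes; in transfer libraries it was -0.18 for MHC class II and -0.12 for TGF-beta genes, and the shift of chemokines was -0.10. No gene of these lists passed over all genes. Adjusted over the list alone, Itga4 of the adhesion list (higher) and Cd14 of the macrophage list (lower) passed in both comparisons, and Stat2 and Stat3 of the JAK-STAT list and Ciita of the class II list (lower) in antibiotic libraries. In antibiotic libraries the epithelial antimicrobial list had -0.27 (0.337) and the epithelial markers -0.04 (0.723).

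For the higher lymphocyte lists, a smaller share of epithelial cells would raise every other cell type alike. The mean of the T, cytotoxic and B cell scores moved further than the mean of the macrophage, dendritic, granulocyte and stromal scores. The gap was 0.70 ± 0.20 in antibiotic and 0.77 ± 0.26 in transfer libraries (log2, SE). Over members above background in all 9 libraries, with 2 granulocyte and 3 stromal genes, it was 0.68 ± 0.20 and 0.74 ± 0.27. Scores also moved unequally between libraries of the same group. From control replicate 1 to control replicate 3 the T cell score went from 8.45 to 6.65 and the macrophage score from 7.26 to 6.54. The test assumed equal movement, so it cannot decide whether such a share is the whole cause or a part. The gap was widest for macrophage markers (1.11 ± 0.30 and 1.25 ± 0.43) and under 2 SE for granulocyte markers (0.44 ± 0.25 and 0.70 ± 0.38). Both gaps use the same control libraries. The lower interferon and presentation lists were not covered by this test. Without control replicate 3, the 9 lists in transfer against control stayed called, and 3 of the 8 in antibiotic against control. Their shifts kept direction but were smaller. The T cell list went from 0.97 to 0.67 in transfer libraries, and the cytotoxic list from 0.84 to 0.56 in antibiotic libraries. For the other 5 the shift fell to a median of 65.2%. The calls hold only at the preset correlation, at which other splits of the same libraries also called lists. The part of control replicate 3 therefore cannot be told apart from a difference between the groups. In the 6 against 3 fit 8 lists were called (adjusted p = 0.607 at the lowest with an estimated correlation), 11 of the 84 splits called as many and the highest other called 11, so chance cannot be excluded for the number of lists. As deviations from group means, the T and B cell scores correlated at 0.975 over the 9 libraries. They moved together within groups, so these lists do not count as separate observations. A larger share of lymphocytes among the isolated cells and a response of the cells to treatment may each contribute and stay open.

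The likeness of antibiotic and transfer fold changes was weighed next. The covariance of 0.562 lay above the highest of 100 simulated data sets, 0.254, but the simulated genes were independent. Of 840 regroupings of the 9 libraries 15 (1.79%) gave as large a covariance of mean log2 differences, all of them with control replicate 3 among the reference libraries, and the highest was 0.695 against 0.655 for the real groups. Without control replicate 3, 22 of 280 regroupings (7.86%) did. Whether the shared controls, through control replicate 3, may account for the likeness therefore cannot be told apart from a transfer profile that resembles the antibiotic one.

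The spike-in totals were weighed last. If capture or imaging varied for whole lanes, panel totals could be expected to follow them, but the log totals correlated weakly over the 9 libraries (Pearson r = 0.14, exact permutation p = 0.712; Spearman rho = -0.05, p = 0.912; adjusted 0.712 and 0.912 over 2 relations). Without transfer replicate 1 and control replicate 1, the libraries farthest from the median spike-in total, r was -0.691. Mean negative-control counts gave r = -0.181 (exact permutation p = 0.643) and rho = -0.267 (p = 0.493). Their r was -0.677 without the same libraries. Lane-wide efficiency and differing spike-in amounts cannot be told apart with 9 libraries, and no biological explanation was tested.

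For the planned comparisons the 10 splits of 6 libraries are too few for a share under 0.05. The gene count was 0 in the real split and at most 0 in the others, in each comparison (as large in 10 of 10). Lists called were 8 against a highest other of 8 in antibiotic against control (2 of 10 as large), 0 against 5 in transfer against antibiotic (10 of 10) and 9 against 11 in transfer against control (3 of 10). For the genes called opposite ways, 100 of 100 splits of the 9 libraries gave as many, since the count was 0.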
